A study of Mus musculus with 287 samples.

How the data were processed

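The series holds Smart-seq3 libraries (full-length RNA sequencing of single cells) from 287 fluorescent cells of mouse cerebral organoids. The organoids were grown from embryonic stem cells and carry MADM cassettes, in which Cre recombination between homologous chromosomes of a dividing progenitor can leave its daughters green and red, with a tamoxifen-inducible Cre driven from the Emx1 locus. Per the labels' protocols, recombination was induced on day 13 with 60 nM 4-hydroxytamoxifen, organoids were collected on day 20, and single green or red cells of located clones were drawn into a glass pipette. The labels give each cell a plate (1, 2 or 3), a clone, a colour, a clone size and a clone type, SN or N. What SN and N stand for is not stated, and no organoid, culture or animal is named.

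The deposited values are raw exon counts and raw intron counts of reads per gene and cell, in 2 tables of 55359 Ensembl gene IDs by 287 libraries, with no scaling recorded. Per the submitters' processing notes, reads were processed with STAR 2.7.9a, R 4.4.0 and genome build GRCm39. The counting tool, the annotation and the use of molecular identifiers are not stated, so counts are read as reads and not as molecules. No annotation of that build was at hand, so no coordinates are given. Gene symbols came from a table of IDs and symbols, in which 52083 of the IDs matched, holding 83.4% of all exon counts. A single ID without a symbol, ENSMUSG00000119584, held 16.5% of exon counts, and the mitochondrial rRNA genes mt-Rnr1 and mt-Rnr2 held 4.62%.

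Everything from here on was computed from those counts. Cells with an exon count in at least 1000 genes were kept, which left 247 of the 284 labelled cells (131 of 147 in SN and 116 of 137 in N clones). The 3 cells without a clone label entered no comparison. Clone 45, with 3 cells labelled plate 2 and 10 labelled plate 3, was put on plate 3 where a clone needed a single plate, and clone 2 kept its labelled size of 3 although 4 of its cells were deposited. No 2 cells had a correlation of log2(CPM+1) above 0.95 (highest 0.888), so no library was taken as a copy of another. Exon counts were summed over the cells of a clone, the lineage unit that the labels name, and clones with at least 2 kept cells were compared: 42 SN clones (127 cells) and 20 N clones (114 cells). Because clones can share an organoid, p-values measure the spread between clones only and may be too small.

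Values in CPM are exon counts per 1e6, out of the total of a cell or the TMM-scaled total of a clone sum. Sums were tested with the quasi-likelihood F test of edgeR 4.0.16 after TMM scaling and the filterByExpr filter, with the Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors (SE, after ±) were derived from that test, as the size of the log2 value over the square root of F. They were not taken from the fitted coefficients. Plate was a term in the SN to N comparison of all cells and in that of the neuron-like cells. Green and red cells were compared as sums per clone and colour, with the clone as block, in the 45 clones with both colours. The clone size test fitted log2 of the labelled size beside plate and clone type. Its filterByExpr filter took the design instead of the groups compared. It kept 17727 genes, against 11914 in the SN to N test of the same clones. Gene lists were tested with camera (limma 3.58.1, correlation 0.01) on the log2 CPM of the clone sums. The 26 lists, the comparisons, their tests and most alternatives were fixed before the data were examined. So was the rule for named genes. Per comparison and direction it took the 12 genes of smallest p past the threshold with a count in at least 10 cells. Where fewer than 3 passed, it took the 3 of smallest p. Added to these were the 2 to 4 leading members of passing lists and of the radial glia, intermediate progenitor, cell cycle, layer and synapse lists, and Emx1. The results of 1 gene that the rule took were left out afterwards and not replaced.

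Cells were clustered by the Leiden method (scanpy 1.11.5, resolution 1, 15 neighbours, 20 principal components, 2000 variable genes). A cluster was named where at least 2 of its 10 leading genes by log2 difference were markers of a class, a rule set after the clusters had been seen. Shares and means per clone were compared by two-sided permutation tests with 100000 resamples, whose smallest p is 1e-05. Similarity was the mean Pearson correlation of log2(CPM+1) over the 2000 most variable genes, within a clone minus between clones of the same plate and type. It was tested with 10000 permutations of cells among clones, whose smallest p is 0.0001. Confidence intervals of shares of cells are 95% Wilson intervals and cover counting error only.

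The tests were tried on simulated data. With counts drawn from the real means and dispersions, the SN to N test recovered 33.3% of genes changed by log2 2 and 78.6% of those changed by log2 4, and 5.94% of its calls were unchanged genes. In the neuron-like comparison these were 1.37%, 18.6% and 30%, in the colour comparison 14.7%, 65.4% and 0%, and for clone size 46.9%, 87.5% and 2.1%. The colour simulation took dispersions fitted with plate alone and drew no clone effect, so its rates may not hold for the real colour fit. Camera called a raised list at an adjusted p of 8.1e-11 and 0 of the 24 others. The simulated genes were drawn independently of each other, so this cannot show how often correlated genes give a false list call. The permutation test gave p under 0.05 in 3.5% of simulated comparisons without a difference and in 95.5% with a difference of 1 SD.

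Alternatives changed the cell filter, the gene filter, the scaling, the tool, the plate term, the clones, the plates, the counts (exon plus intron) and the clustering. DESeq2 1.42.0 and limma-voom were the other tools. Choices added after seeing the data left out the unnamed ID with mt-Rnr1 and mt-Rnr2, left out cells in which that ID took over 40 percent of exon counts, drew 2 cells per clone, thinned each cell to 100000 exon counts, and added the mitochondrial share, the share of the unnamed ID and the scores of neuronal against radial glia genes and of deep-layer against upper-layer genes. For regroupings of the samples, up to 100 draws were fitted per comparison. Those of the colour comparison kept the dispersions of the real colours.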

Results

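The data describe single cells drawn by pipette from green or red fluorescent clones in mouse cerebral organoids, with recombination induced on day 13 and collection on day 20. The labels assign 51.8% of the cells that have a clone label to 46 clones of type SN and 48.2% to 22 clones of type N, and leave 3 cells without a clone. Labelled clone sizes ran from 2 to 6 cells in SN clones (median 3) and from 4 to 19 in N clones (median 6.5), so the types overlap in size only from 4 to 6. Of the labelled cells, 96 lay on plate 1, 93 on plate 2 and 95 on plate 3. Exon counts per labelled cell ranged from 4 to 13040432, with a median of 1257572.5 and quartiles of 213260.25 and 3782482. Of the SN cells 89.1% had a count in at least 1000 genes, and of the N cells 84.7% did. Among these kept cells, total exon counts ran from 6171 to 13040432, with a median of 1365828 in SN cells and 1887116.5 in N cells.

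Most cells had counts of genes of young cortical excitatory neurons, and most also had counts of several radial glia genes. Stmn2, a microtubule regulator of growing neurons, was counted in 96.8% of the kept cells (95% interval 93.7 to 98.4), and Neurod6, a transcription factor of cortical excitatory neurons, in 87.4% (82.7 to 91). The deep-layer gene Bcl11b was counted in 77.3% of them (71.7 to 82.1). The radial glia gene Fabp7 was counted in 95.5% (92.2 to 97.5), and Stmn2 and Fabp7 together in 92.7%. Vim and Sox2, also of radial glia, were counted in 93.1% and 66.4%, and the cell cycle gene Top2a in 66.4%. Such shares include very low counts, since 20.2% of all exon values above 0 were counts of 1 to 3. Genes of other cell types ranged widely: Reln of Cajal-Retzius cells was counted in 62.8%, the imprinted H19 in 56.7%, Olig2 of the oligodendrocyte lineage in 79 cells (32%), Col1a1 of mesenchyme in 74 (30%), Ttr of choroid plexus in 68 (27.5%), Gad1 of GABAergic neurons in 58 (23.5%), Cldn5 of endothelium in 6 (2.43%) and the pluripotency gene Pou5f1 in 5 (2.02%). Emx1, from whose locus the Cre is driven, was counted in 84 cells (34%, 28.4 to 40.1).

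Clustering gave 7 clusters, of which only 2 could be named from their leading genes. A neuron-like cluster of 39 cells led with Gap43, Mapt and Stmn2, and a progenitor-like cluster of 38 cells led with Fabp7 and Dbi, at median depths of 3120526 and 1525436.5 exon counts. The other 170 cells lay in clusters that could not be named, among them 53 cells led mostly by ribosomal protein genes and 47 led by the unnamed ID. Nearly all cells of both clusters had counts of Stmn2 and Fabp7, which differed in level: medians in neuron-like and progenitor-like cells were 4074 and 2140 CPM for Stmn2 and 1028 and 2724 CPM for Fabp7, genes that also served to name the clusters.

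The SN to N comparison of all cells asks whether the 2 labelled kinds of clone differ in expression. Radial glia genes were 1 of the 2 lists called, and 19 of the 20 measured members lay above 0, with a median log2 difference of 0.41. Fabp7, a fatty acid binding protein of radial glia, averaged 3025 CPM in SN clones (SD 3719, n = 42) and 1567 CPM in N clones (SD 768, n = 20), a log2 difference of 0.96 ± 0.36 (SE). Its medians, 1741 and 1429 CPM, lay closer together. Hes5, a Notch target that holds progenitors undifferentiated, differed by 1.20 ± 0.77, Ddah1 by 0.81 ± 0.44 and Dbi by 0.54 ± 0.29. Here too the medians in SN and N clones lay close: 14.3 and 13.9 CPM for Hes5, 75.1 and 65.2 CPM for Ddah1, and 388 and 370 CPM for Dbi. Camera called the list at an adjusted p of 0.0001815. Of its members 0 passed over all genes and 0 adjusted over the list alone, and the call was lost with an estimated correlation (adjusted p = 0.804 with an estimated correlation). The radial glia call was also lost when each cell weighed equally within its clone (adjusted p = 0.156, with 13 of 20 members above 0).

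**Figure D1:**
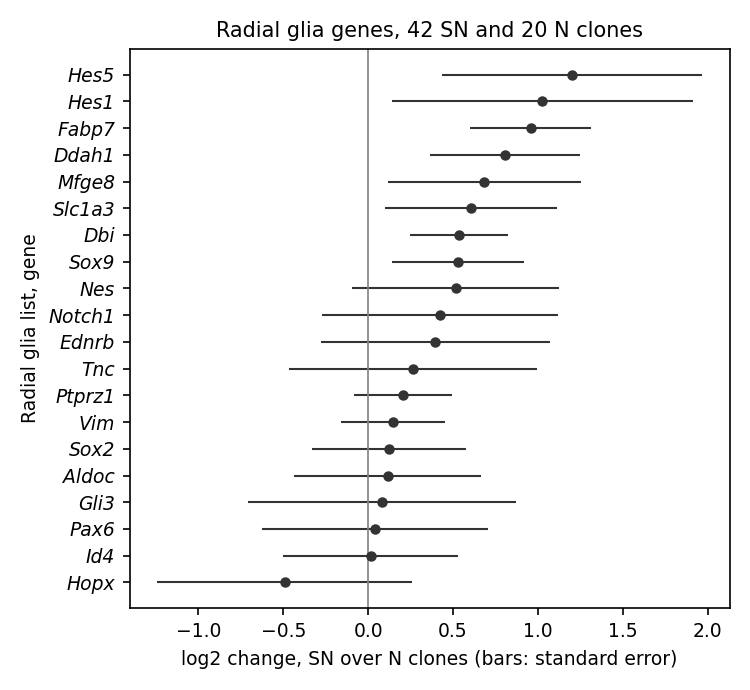
Log2 difference (SN over N clones) of the 20 radial glia genes on the horizontal axis, 1 gene per line, with standard errors as bars, from edgeR on sums of 42 SN and 20 N clones. Of the 20 points 19 lie above 0, with Fabp7 at 0.96 and Hopx at −0.49, and no single gene passed the test.

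The late progenitor list, which holds genes of gliogenic and late radial glia, was the other list that camera called (adjusted p = 0.0133). Of its 10 members 7 lay above 0 with a median of 0.16, and 6 of these 7, Fabp7, Sox9, Slc1a3, Ptprz1, Tnc and Aldoc, also stand in the radial glia list. Zbtb20, a transcription factor of late progenitors and hippocampal neurons, went the other way with 305 CPM in SN and 606 CPM in N clones (log2 −0.93 ± 0.35), as did Nfix (−0.48 ± 0.29) and Nfib (−0.25 ± 0.20), which were named after their values had been seen. Over all genes 0 members passed, and 2, Zbtb20 and Fabp7, passed adjusted over the list alone. The adjusted p was 0.804 with an estimated correlation.

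The other 23 lists did not pass, with adjusted p from 0.333 to 0.940. Immature excitatory neuron genes lay mostly on the N side (1 of 10 above 0, median −0.47, adjusted p = 0.333), while Notch pathway genes lay mostly on the SN side (6 of 9, median 0.42, adjusted p = 0.333). Intermediate progenitor genes were split, with Mfng at 1.51 ± 1.15 and Hes6 at 0.54 ± 0.43 but only 4 of 13 members above 0. The median of Mfng was 0 CPM in SN and 0.938 CPM in N clones. Among cell cycle genes 9 of 20 lay above 0, Pcna at 0.29 ± 0.36 and Hmgb2 at 0.24 ± 0.34. The deep-layer genes Foxp2 (1.75 ± 0.87) and Hs3st4 (−0.89 ± 0.76) went opposite ways, and the upper-layer genes Inhba (−1.93 ± 0.91) and Lmo4 (−0.36 ± 0.25) lay on the N side. The median of Foxp2 was lower in SN clones (0.796 CPM) than in N clones (1.09 CPM). Of the synapse genes, Gria2, an AMPA receptor subunit, averaged 349 CPM in SN and 527 CPM in N clones (−0.55 ± 0.25), and Snap25, of the vesicle fusion machinery, 150.6 and 229.1 CPM (−0.67 ± 0.32). Emx1 averaged 14.2 and 19.7 CPM (−0.57 ± 0.81). For the cell cycle, intermediate progenitor, pan-neuronal, immediate early, p53 response, oligodendrocyte lineage and microglia and endothelium lists camera ranked the members upward although their medians lay below 0. The median and mean of the synapse, GABAergic neuron and choroid plexus lists differed in sign.

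Gene by gene, edgeR's quasi-likelihood test passed 0 of 11914 genes (smallest adjusted p = 0.121). At an unadjusted p under 0.05, 39 genes (0.327% of those tested) were higher in SN and 1.74% of those tested were higher in N clones. DESeq2's Wald test passed 2 genes, both higher in N, and limma-voom, whose values lay toward N as a whole, 43, of which 42 were higher in N. The smallest p on the N side were those of Fn3krp, which acts on glycated proteins (1.08 CPM in SN, 11.1 CPM in N, log2 −3.60 ± 0.76), Spata2l (−3.39 ± 0.79) and Ddx28, a mitochondrial RNA helicase (−3.83 ± 0.93). On the SN side they were those of Spin2c (4.10 ± 1.39, counted in 25 cells) and the mitochondrial rRNA genes mt-Rnr2 (0.54 ± 0.20) and mt-Rnr1 (0.62 ± 0.23). None of these 6 passed the adjustment. The median log2 difference of all genes was −0.11, and 0.07 with the size factors of DESeq2, under which 0.982% of genes were higher in SN and 1.13% higher in N at an unadjusted p under 0.05. Limma-voom moved the median of all genes to −0.54, and the values of mt-Rnr2 (−0.15), Fabp7 (−0.21) and Dbi (−0.045) changed sign under it while staying above that median. With equal weight per cell the values of Gria2 (0.29) and Zbtb20 (0.21) changed sign.

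Within the neuron-like cells, the comparison asks whether SN and N clones differ apart from their mix of cells. It rested on 3 SN and 4 N clones with 2 or more such cells. Mitochondrial transcripts led on the SN side: mt-Co1, a subunit of complex IV, averaged 3977 CPM in SN clones (SD 1353, n = 3) and 1014 CPM in N clones (SD 620, n = 4), a log2 difference of 2.09 ± 0.40, with mt-Nd2 at 1.92 ± 0.53 and mt-Rnr2 at 1.88 ± 0.51. On the N side stood Ubr1, a ubiquitin ligase of the N-degron pathway (21.9 and 220 CPM, −3.58 ± 0.99), the paraspeckle gene Pspc1 (−5.79 ± 1.80) and Mnt (−6.12 ± 1.95). Of 10457 genes edgeR passed 0, with 72 (0.689%) higher in SN and 1.84% higher in N at an unadjusted p under 0.05. Limma-voom passed 0, and DESeq2 passed 190, of which 81.1% were higher in N. All of the 24 lists tested had an adjusted p of 0.842 and 0 passed. With cells of at least 2000 genes, clustered anew into another neuron-like class, Pspc1 (0.78) and Mnt (0.59) changed sign. With single-cell clones included Ubr1 (0.66) did.

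The class genes spread widely in these 7 clones. Among radial glia genes Hes1 stood at 5.43 ± 2.11 and Hopx at −3.86 ± 2.44, among intermediate progenitor genes Neurog2 at −8.20 ± 3.47 and Mfng at −3.68 ± 3.26, and among cell cycle genes Top2a at 1.26 ± 1.01 and Rrm2 at −2.77 ± 1.89. Some of these large values are ratios to levels near 0. Means in SN and N clones were 5.82 and 0.152 CPM for Hes1 and 0.532 and 31.5 CPM for Neurog2, each counted in 7 of 17 cells. For Mfng they were 1.13 and 11.1 CPM, counted in 4 cells. The deep-layer genes Ldb2 (1.89 ± 1.32) and Crym (−3.82 ± 2.28) went opposite ways, as did the synapse genes Grin2b (0.73 ± 0.68) and Gria2 (−0.88 ± 0.42), and the upper-layer gene Mef2c stood at 1.82 ± 0.94. Emx1 stood at 0.31 ± 2.34. All of these had an adjusted p of 1 in edgeR's test.

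Neuron-like cells made up a mean of 16.2% of an SN clone (SD 24.3, n = 42) and 17.3% of an N clone (SD 17.5, n = 20; permutation p = 0.865, adjusted p = 0.865). Progenitor-like cells made up 18.3% (SD 26.2) and 11.4% (SD 14.8; permutation p = 0.279, adjusted over the 2 classes 0.557). Both classes occurred together in 3 SN and 7 N clones. Neither share differed by more than the spread between clones. Of the kept cells, 170 belonged to neither class.

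Mitochondrial transcripts made up 6.96% of exon counts in SN clones (SD 3.03, n = 42) and 4.73% in N clones (SD 2.31, n = 20; permutation p = 0.005). The measure was chosen after seeing the data and was 1 of 6 compared together, over which its adjusted p was 0.03. On plate 1 alone the difference was 3.65 percentage points (p = 0.0137, permutation test), on plate 2 it was 1.59 (p = 0.237) and on plate 3 it was 1.06 (p = 0.351). Most of it came from mt-Rnr1 and mt-Rnr2, which together made up 6.12% in SN and 4.06% in N clones (p = 0.00397), whereas mitochondrial mRNA and tRNA genes made up 0.832% and 0.674% (p = 0.11). The p-values of these 2 parts are unadjusted permutation p. Gene by gene, no mitochondrial gene passed the permutation test after adjustment over these genes, with mt-Rnr1 and mt-Rnr2 each at an adjusted p of 0.0995.

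**Figure D2:**
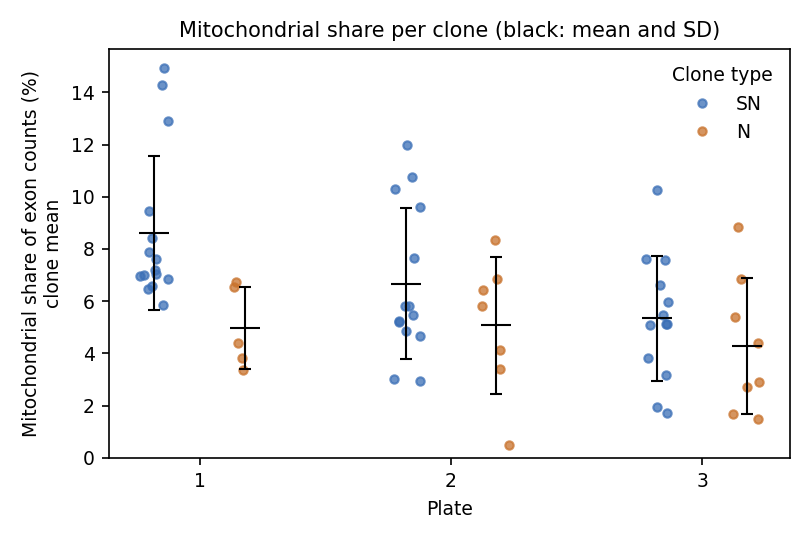
Mitochondrial share of exon counts (percent, mean over the cells of a clone) on the vertical axis for SN and N clones of plates 1, 2 and 3, 1 point per clone, with mean and SD in black. The means of SN and N clones were 8.63 and 4.98 on plate 1, 6.66 and 5.07 on plate 2, and 5.34 and 4.28 on plate 3.

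Introns took 28.2% of a cell's counts in SN clones (SD 8.15) and 29.2% in N clones (SD 7.73; permutation p = 0.654), a share that reads unspliced or nuclear RNA. The difference was 0.35 percentage points on plate 1, −0.98 on plate 2 and −0.67 on plate 3. In clones of size 4 to 6 the intron share was lower in SN, by −5.98 percentage points (p = 0.0396). SN clones had a mean of 6507 detected genes per cell (SD 2512) and N clones 7002 (SD 2567; p = 0.473), and 4597 and 4958 when each cell was thinned to 100000 exon counts (p = 0.349). The difference in detected genes was 1177 on plate 1, −2491 on plate 2 and 143.3 on plate 3. The share of the unnamed ID (19.5% and 20.6%), the neuronal minus radial glia score (1.24 and 1.36) and the deep-layer minus upper-layer score (−0.09 and −0.12) had an adjusted p of 0.752. Their differences on plates 1, 2 and 3 were −1.48, 4.61 and −1.14 percentage points for the unnamed ID, −0.28, −0.06 and −0.10 for the neuronal score, and 0.110, 0.0988 and −0.138 for the layer score.

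**Figure D3:**
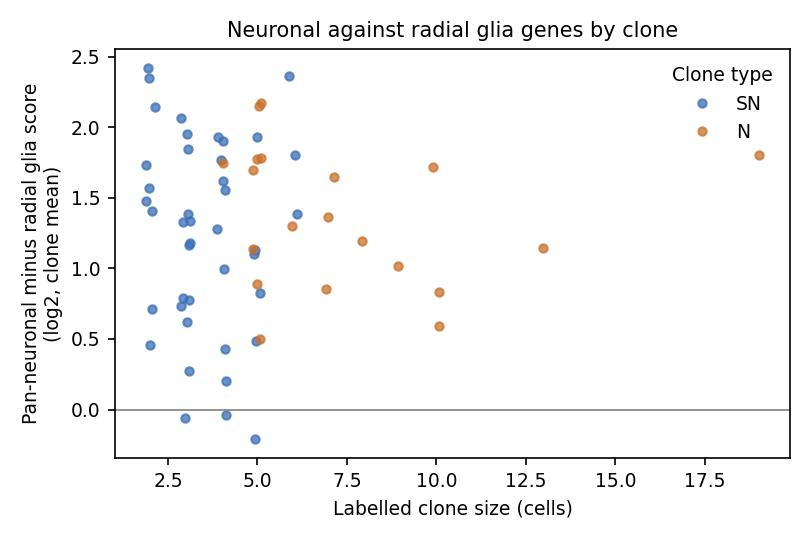
Pan-neuronal minus radial glia score (difference of mean log2 values, mean over the cells of a clone) on the vertical axis against labelled clone size in cells, 1 point per clone, shifted slightly sideways for legibility. The SN clones (mean 1.24, SD 0.70, n = 42) and N clones (mean 1.36, SD 0.49, n = 20) overlap over their range.

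Green and red cells of a MADM clone descend from the 2 daughters of 1 recombined progenitor, so their comparison asks whether sister lineages differ. Mitochondrial rRNA was lower in green cells: mt-Rnr2 averaged 25664 CPM in green and 34656 CPM in red cells (log2 −0.51 ± 0.14, n = 45 clones, p = 0.000354), and mt-Rnr1 25477 and 35002 CPM (−0.60 ± 0.16, p = 0.000452). Bmi1, a Polycomb gene that keeps stem cells renewing, averaged 28.5 CPM in green and 8.22 CPM in red cells (4.16 ± 1.18) and was higher in green in 28 of 45 clones. Gm12715 (1.31 ± 0.45) and Ubp1 (3.10 ± 1.11) were the next on that side, and Cmtm3 lay on the red side (−3.53 ± 1.32). EdgeR passed 0 of 7437 genes, all 6 of these at an adjusted p of 1, with 96 genes higher in green and 26 higher in red at an unadjusted p under 0.05. Of the genes at that p, 3.72% were higher in red in SN clones alone and 89.6% in N clones alone, a contrast that was not tested. No other tool was completed for this comparison.

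Per clone, the mitochondrial share averaged 5.92% in green cells (SD 3.72) and 7.62% in red cells (SD 4.11; two-sided sign-flip permutation p = 0.00886), a measure chosen after seeing the data. Green was lower in 29 of 45 clones. The difference averaged −2.32 percentage points in 31 SN clones and −0.32 in 14 N clones, and these did not differ by more than the spread between clones (permutation p = 0.136). Of the other 3 measures compared by colour, the intron share (p = 0.539), the unnamed ID (p = 0.105) and detected genes (p = 0.68) showed no difference beyond that spread. For detected genes the green minus red difference averaged 1281 in SN and −1790 in N clones (permutation p = 0.0689 between the types).

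The clone size comparison asks which genes go with the number of labelled cells, beside clone type. Of 17727 genes edgeR passed 1.37%, of which 86 genes rose and the other 64.5% fell with log2 size, but each named gene was counted in few of the cells, and 12 of 40 regroupings of the sizes, the real one included, gave as many genes. Fgf5, a growth factor of the early embryo, rose by 6.63 ± 1.07 per doubling (adjusted p = 7.5e-05) and was counted in 10 cells. Pard6b, a polarity gene, rose by 6.49 ± 1.44 (22 cells), Rassf7 by 5.25 ± 1.07 (26 cells) and Pcdh20, a protocadherin, by 5.06 ± 0.97 (10 cells). Lipt1, Gm38251, Gm26952, Zfp652os, 4930558J18Rik, Mbnl3, Tmem159 and the unnamed ENSMUSG00002076103 rose as well, in 10 to 20 cells each. Cubn, an endocytic receptor, fell by 5.26 ± 0.85 (adjusted p = 7.5e-05, 11 cells), Pax7, a transcription factor of dorsal neural tube and muscle, fell by 6.02 ± 1.10 (10 cells) and Nanos2, a germ cell gene, fell by 7.09 ± 1.30 (15 cells). Gm43052, Creb3l3, St8sia6, Gm42478, Pdia2, AC154442.1, P2ry6, Gm19345 and Msh4 fell, in 10 to 19 cells each.

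Fewer genes passed without the largest clone or within a clone type. Without clone 16, an N clone of size 19, edgeR passed 46 genes, in SN clones alone 6 and in N clones alone 0, where 5.12% of 18051 genes lay above and 1.45% below 0 at an unadjusted p under 0.05. DESeq2 passed 88 genes.

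Cells of 1 clone resembled each other slightly more than cells of other clones of the same plate and type, which bears on whether lineage shapes expression. The mean correlation was 0.160 over 508 pairs within clones and 0.145 over 4498 pairs between clones, a difference of 0.0147 (permutation p = 0.0028). Without clone 16, the N clone of size 19, it was 0.0257, and with each clone weighted equally 0.0398 (p = 0.0001 for both, the smallest that 10000 permutations can give). The difference was 0.0264 after each gene was regressed on depth and detected genes (p = 0.0001), and 0.00889 over the 5000 most variable genes (p = 0.139). It was 0.0726 over 14 within-clone pairs of neuron-like cells (p = 0.0001). Against cells of other clones with library numbers at most 5 apart, the difference was 0.00305 (shift test p = 0.948), and 0.0147 after the regression (p = 0.0057). Within a clone, cells of the same colour had a correlation of 0.148 and cells of different colours 0.161, a difference of −0.0132 (permutation p = 0.175), so sister lineages were not told apart by this measure.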

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

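The mitochondrial share, its tests within plates and within neuron-like cells, the N-side share of genes by scaling, clone size and regrouping, the comparison of similarity after regression on depth and that of its neighbouring libraries, and the count of regroupings for the SN to N genes of all cells were chosen after their results were seen.

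The 3 cells without a clone label held 1689914, 5976683 and 2257 exon counts, and they are listed here because no comparison uses them. Clone values were searched for a lone extreme only in groups of 4 to 10 clones, which were the N clones of each plate. Over the mitochondrial, intron and unnamed ID shares and detected genes these made 12 groups, and 0 lone values were found. SN clones were not searched, since each plate held more than 10 of them.

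Radial glia and late progenitor genes were the 2 lists called in SN against N clones, and 30 of 100 regroupings of the clones gave as many lists, the highest of the others 10, so chance is not excluded. Where the real count was 0, every regrouping reaches it, so the counts decide nothing about chance: single genes of all cells (100 regroupings, highest other 2), single genes and lists of neuron-like cells (35 splits each, highest others 1 and 2) and green against red (25 colour flips, highest other 0). Of the colour flips 15 were as unbalanced as the real colours between green and red at an unadjusted p under 0.05. For clone size 12 of 40 regroupings gave as many genes as the real sizes (1.37% of 17727 genes), with 458 genes the highest of the others, so chance is not excluded for Fgf5, Cubn and the other genes named there. Whether such counts come from a structure among the clones, from the largest clone (46 genes passed without it) or from the test on genes counted in few cells was not tested. The clone size filter, set by the design and not by groups, kept 17727 genes, against 11914 for SN to N.

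Genes with an unadjusted p under 0.05 lay mostly on the N side, 84.1% of them, in the comparison of all cells, and of 100 regroupings only the real one (1) was as unbalanced. The sum of an N clone holds more cells on average. With 2 cells drawn per clone, a mean of 50.6% of such genes lay on the N side over 20 draws (SD 13.8, range 26.1 to 74.5). With all cells kept, the share was 53.6% under the size factors of DESeq2, and in clones of size 4 to 6, where the types overlap, it was 72.8%. The number of cells in the sum, the scaling and a difference between the clone types therefore cannot be told apart as sources of the imbalance.

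Mitochondrial transcripts, mainly mt-Rnr1 and mt-Rnr2, took a larger share in SN clones. Plate alone is argued against by the permutation within plates (p = 0.00343), and depth by the difference that remained after regression on exon counts and detected genes (2.07 percentage points, p = 0.00968, permutation test). Without plate 1 the difference was 1.38 percentage points (p = 0.113), so part of it lies there. Whether rRNA capture differed or mitochondrial transcripts as a whole cannot be told apart, since the SN over N ratio was 1.23 for the mRNA and tRNA part (95% bootstrap interval 0.963 to 1.67) and 1.51 for rRNA (1.19 to 1.97). The mix of neuron-like and other cells as the whole source is argued against by neuron-like cells alone, with 8.62% in 16 SN and 4.98% in 13 N clones, a difference of 3.64 percentage points (p = 0.0183). In clones of size 4 to 6 the difference was 3.565 percentage points (19 SN and 10 N clones, p = 0.00335, permutation test). Green cells made up 58.0% of kept SN and 66.4% of kept N cells. After regression on colour the difference was 2.15 percentage points (p = 0.00716, permutation test). Both checks, chosen after seeing the data, argue against clone size or the colour mix as the whole source. The clone type itself and the state of the drawn cell stay open and may each contribute.

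Cells of 1 clone were more alike than cells of other clones. Depth is argued against, since after regression on it the difference was 0.0264. Cells of different clones whose library numbers lay within 5 of each other were nearly as alike as cells of 1 clone in the unadjusted values (difference 0.00305, shift test p = 0.948), which is consistent with libraries made side by side as a source. After regression on depth cells of 1 clone exceeded such neighbours by 0.0147 (shift test p = 0.0057). RNA from neighbouring cells in the pipette cannot be told apart from lineage, because cells of a clone lie near each other and 92.7% of cells held both Stmn2 and Fabp7, and neighbouring library numbers may also share an organoid.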

How the results depend on the processing

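The N clones alone, the SN clones alone, the equal weighting and the size-19 clone left out in the similarity comparisons, the single clones left out in turn, the unnamed ID and mitochondrial rRNA left out, cells with over 40 percent of that ID left out, 2 cells drawn per clone, the thinning and all settings of the mitochondrial share, the unnamed ID share and the 2 scores were chosen after seeing the data. Of 118 alternatives of the comparisons 89 kept direction and side of the threshold or, for gene and list counts, a similar count. Of the rest, 21 changed such a count, 5 reversed, 2 lost and 1 gained significance. Of 1014 alternatives of single genes 906 kept direction and side. Of the rest, 64 lost significance (all clone size genes), 22 gained it and 22 reversed. For SN against N clones no paired analysis was possible, since replicate numbers only name cells. Colours were compared within clones. Depth limits the rest: a gene counted in few cells is 0 in most clones, and intervals cover counting error only.

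In the SN to N comparison of all cells, with 0 genes passing, the count was 6861 without the filter on low counts, where 19 other regroupings gave up to 6327. Which genes were called there was not examined. It was 42 with genes counted in 10 percent of cells, 43 by limma-voom, 2 by DESeq2, 2 with cells of at least 2000 genes and 1 with clones of at least 3 cells. Among neuron-like cells it was 7 without the filter, 190 by DESeq2, 3 with genes counted in 10 percent of cells and 2 on mean log2 values, and 0 with any of the 7 clones left out. For green against red it was 1 without the filter and 5 in neuron-like cells (3 clones). For clone size 1.37% of the genes tested passed, and this became 9.43% without the filter, 3.24% with size not log transformed, 0.664% without the type term (95 genes up, 16 down), 0.496% by DESeq2 (88 genes), 0.291% without the size-19 clone (46 genes), 0.0458% in SN clones (6 genes) and 0 in N clones. The 2 gene lists became 0 with an estimated correlation and 0 on mean log2 values. The cause was not tested beyond this.

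The intron share difference was 0.449 with no filter on cells, a reversal, and −5.98 in clones of size 4 to 6, where it passed. Detected genes reversed to 185.9 with no filter on cells and to 342 in neuron-like cells. The deep-layer minus upper-layer score reversed to −0.011 in clones of size 4 to 6. The neuron-like share reversed to 4.17 with cells of at least 2000 genes, clustered anew (26 neuron-like cells). Similarity within clones rose from 0.0147 to 0.0257 without the size-19 clone and to 0.0398 with clones weighted equally, and was 0.00889 over 5000 genes and 0.0148 in N clones, both no longer passing. Same-colour similarity reversed to 0.0194 in neuron-like cells, with only 1 same-colour pair. The cause was not tested.

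Among genes of the all-cell comparison the log2 value reversed under limma-voom, whose median over all genes was −0.54, for mt-Rnr2 (−0.15), Fabp7 (−0.21) and Dbi (−0.045), in clones of size 4 to 6 for Foxp2 (−0.82), on mean log2 values for Gria2 (0.29) and Zbtb20 (0.21), and without plate 1 for Emx1 (0.21). Among neuron-like cells it reversed with cells of at least 2000 genes for Pspc1 (0.78), Mnt (0.59), Neurog2 (0.67), Rrm2 (0.10), Top2a (−1.05), Ldb2 (−2.78), Mef2c (−1.52) and Emx1 (−10.46). That setting leaves 3 SN and 2 N clones and clusters anew, so filter and neuron-like class changed together. With single-cell clones included it reversed for Ubr1 (0.66), without the size-19 clone for Crym (0.093), at resolution 1.5 for Emx1 (−0.19) and without plate 3 for Emx1 (−0.74). With single clones left out Crym ranged from −5.44 to 0.093 and Emx1 from −0.75 to 1.39. The cause was not tested.

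Not run: DESeq2 for green against red, whose fit was not completed, and for neuron-like cells the settings with no filter on cells, clones of at least 3 cells, clones of size 4 to 6, without plate 1 and resolution 0.5, which leave too few clones or no named class. Class shares could not be compared at resolution 0.5 or with no filter on cells, since no cluster was named, and the neuron-like share could not be compared with the unnamed ID and mitochondrial rRNA left out of the clustering.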

Other observations

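The test of genes that differ between clones, the choice of the genes named here and the thinking behind the imprinted genes came after the main comparisons had been seen.

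Some genes differed widely in level between clones. Ttr, the thyroid hormone carrier made by choroid plexus, was above 10 CPM in 52 cells and in all 9 cells of clone 17, an N clone on plate 1 with a mean of 1126 CPM, while the median clone had 0. Hbb-bh1, an embryonic globin, reached 340 CPM in clone 16, where 11 of 16 cells were above 10 CPM, and the 5 highest clones held 78.9% of its sum over clones. H19, an imprinted noncoding RNA of early tissues, reached 2424 CPM in clone 25 against a median of 33.8 CPM, and Crabp2, a retinoic acid binding protein, 360 CPM in clone 27 against a median of 0. Apoe, a lipid carrier of glia, reached 2182 CPM in clone 23 against a median of 113.8 CPM, and the neuronal tubulin Tubb3, counted in all 62 clones, 2915 CPM in clone 22 against 811 CPM. These highest values rest on few cells, 2 each in clones 25, 27 and 22 and 3 in clone 23.

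For the tests between clones, the log2(CPM+1) values of each gene were first regressed on log2 exon counts and detected genes. Over 11077 genes counted in at least 20 percent of the cells, an F test of the residuals between clones of the same plate and type passed 1.83% after Benjamini-Hochberg adjustment. Of 100 regroupings of the cells only the real one (1) gave as many, and the highest of the others was 32 genes (0.289%). The highest single F is less telling: it was 5.92 for Ttr, and 6 of the other regroupings had a gene above that, up to 11.6. In a fit with plate but not type as stratum, with clone labels shifted along the order of libraries, the real labels gave 2.1% of genes and the highest of the other shifts 1.58%, again 1 of 100. After the regression on depth, these counts point to clones that differ in expression levels beyond what neighbouring libraries share. This is a hypothesis found and tested on the same cells. Unadjusted values were not put to these tests. In them, the similarity of cells within a clone hardly exceeded that of neighbouring libraries (difference 0.00305, shift test p = 0.948). Lineage, a shared place in the organoid, a shared organoid and RNA from neighbours were not separated, and ribosomal genes such as Rpl31 and Rpl38 were among the leading genes.

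Because MADM cassettes on chromosome 11 can leave green and red cells with copies of opposite parental origin, imprinted genes of that chromosome were compared as a hypothesis. Grb10 stood at 1.19 ± 1.11 (log2, green over red, n = 45 clones), Zrsr1 at −0.48 ± 1.28 and Commd1 at 0.11 ± 1.08, and Ddc could not be tested. The smallest p adjusted over these genes was 0.858, and the standard errors are too wide to tell whether the levels differ.

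The mitochondrial share outside the unnamed ID was also compared, as a check chosen after seeing the data: the difference between SN and N clones was 2.35 percentage points (p = 0.0158, permutation test).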
